A study of Homo sapiens with 6 samples.

How the data were processed

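Total RNA of MDA-MB-231 cells was labelled with biotin after reverse transcription and hybridised to 6 single-colour Affymetrix arrays of 54675 probe sets, per the labels' protocols. The cells had been transduced with a lentivirus for enhanced GFP or for GATA3 and GFP, and sorted for GFP. The 3 GFP control arrays and the 3 arrays labelled GATA3 were taken from the group and replicate labels of the samples. The deposited values, read as log2, were made with GCRMA, per the submitters' processing notes, with the version not given in the sources used here. Neither the file header nor the labels state the scale of the deposited values. The log2 reading is what GCRMA gives and what their range fits. GCRMA subtracts a background estimated from probe sequence and leaves many probe sets at a common floor. The floor was 2.16 on every array and held 18325 to 18892 probe sets per array. Some probe sets repeated a higher value of their own, such as 4.42 on all arrays for a PAX8 probe set. A value over 4 therefore need not be signal. Array medians were 2.69 to 2.77, and 23603 to 23709 probe sets per array lay over 4. The number of arrays limits the precision.

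Values were used as deposited, with no further scaling. The 62 control probe sets were left out of the tests. A probe set was tested if it lay over 4 on the log2 scale in at least 3 of the 6 arrays, whatever their group, which left 23785 tested and 30828 not tested. A probe set not over 4 in any array of 1 group thus entered only if all 3 arrays of the other lay over 4. The counts of measured list members therefore leave out genes dim in both groups. Gene symbols came from the platform annotation, in which 41091 probe sets had 1 symbol, 1801 several and 11721 none. The symbols were checked against a current gene table, and 0 needed an update. Of the tested probe sets, 20139 had 1 symbol, and no gene was named from a probe set with several. A gene was represented by its tested probe set with the highest mean over all 6 arrays. Of 5427 genes with over 1 tested probe set, 16 had probe sets that passed the threshold in opposite directions, none of them a gene named here.

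The arrays labelled GATA3 were compared with the GFP control arrays with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. A fold was computed from the difference of mean log2 values. Where all arrays of a group were at or under 4, taken as the detection level, the fold was given as a lower bound, the mean of the brighter group against 4.

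The 25 gene lists were fixed before the data were examined. They were tested with limma's camera with its preset correlation of 0.01, two-sided, on 1 probe set per gene. Adjustment was over the 24 lists with at least 3 measured members. Their members were counted at the adjusted p over all tested probe sets and again adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes, were run beside it. None of the 8 list calls held with an estimated correlation. For the mesenchymal, basal, unfolded protein and proliferation lists that correlation was -0.0702, -2.66e-05, -0.00714 and 0.00873, below the preset. A higher correlation between members cannot account for those losses. With an estimated correlation, camera also takes its p-values from the degrees of freedom left by the few arrays. With the preset one it takes them from the far larger number of genes. The estimated form is therefore weaker for all 8 lists, so these losses alone do not show that a call is fragile. How much of each loss came from this was not tested. The estimate was above the preset for the junction (0.156), MAPK (0.137), interferon (0.122) and hypoxia (0.0224) lists.

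The genes named were chosen by a rule fixed before the data were examined. GATA3 and LOX were named whatever their values. The 12 genes with the largest rise and the 12 with the largest fall were named among those past the threshold with no overlap between the arrays of the groups. Their rank used the fitted log2 change, also where a group lay under the detection level, and is uncertain there. Of each list, up to 4 members with the largest change past the threshold were named. Where none passed, the measured member with the highest mean was given. LOXL2 and LOXL3 were named after their values had been seen. So were the luminal genes NAT1, KRT8, KRT18 and MLPH, and those that did not pass or had no tested probe set.

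The limma and camera steps were tested on simulated data. Among 23785 simulated probe sets, 80 were changed by a log2 size of 0.5, 80 by 1 and 40 by 2. Of these, 20%, 73.8% and 92.5% were recovered, and 4.27% of calls were false. In the measured data 6027 probe sets passed the threshold, far more than were changed in the simulation, so these rates need not hold there. Camera called 0 of 40 unchanged simulated sets and called a set of 20 raised by 0.5. These results do not show how either step performs with 1 array that stands apart or with correlated list members. The alternatives were other filters, scalings, variance models and array weights (1 form of them added after seeing the data), a replicate block, the raw-file date set as a block, other choices of probe set and set test, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.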

Results

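Gene expression was measured on 6 arrays in MDA-MB-231, an established human breast cancer cell line of basal, mesenchymal-like character. The cells had been transduced with a lentivirus carrying enhanced green fluorescent protein (GFP) alone, or GATA3 together with GFP, and sorted for GFP. GATA3 is a transcription factor of the luminal cells of the mammary gland. There were 3 arrays for the GFP control and 3 labelled GATA3. The title of the series states that GATA3 moves basal cells towards a luminal subtype and limits metastasis through lower lysyl oxidase, and the comparison bears on both statements. The design text describes 2 samples sent in triplicate, and the labels do not say that the triplicates were separate cultures. The p-values below therefore measure the spread between these arrays, which may be technical. Values are GCRMA expression values read as log2, and 3 arrays per group limit the precision.

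The arrays of each group resembled each other more than those of the other group. Over the 23785 probe sets tested, the correlation between GFP control arrays was 0.995 to 0.996, and that between GATA3 replicates 1 and 2 was 0.997. GATA3 replicate 3 correlated with those 2 arrays at 0.984 and 0.986, and arrays of different groups correlated at 0.940 to 0.959. GATA3 replicate 3 had a 75th percentile of 7.78, against 7.97 to 8.04 on the 5 other arrays, and it alone carries the second raw-file date set. The log2 ratio of 3' to 5' control probe sets was -0.052 ± 0.020 (SD, n = 3) in the GFP control and -0.012 ± 0.013 (SD, n = 3) in the arrays labelled GATA3 for GAPDH (two-sided exact permutation p = 0.1). For ACTB it was 0.53 ± 0.08 (SD, n = 3) and 0.50 ± 0.07 (SD, n = 3), with a two-sided exact permutation p = 0.7. The smallest p that 3 arrays against 3 allow in that exact test is 0.1.

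GATA3 itself was lower, not higher, in the arrays labelled GATA3. The probe set with the highest mean (209604_s_at) read 9.39 ± 0.06 (SD, n = 3) in the GFP control and 7.73 ± 0.35 (SD, n = 3) in the arrays labelled GATA3. This was a log2 change of -1.66 (SE 0.18), 3.16-fold lower, with an adjusted p of 0.00238. A second probe set (209602_s_at) fell by 1.48 on the log2 scale (SE 0.20), from 4.73 ± 0.34 to 3.24 ± 0.19 (SD, n = 3), with an adjusted p of 0.00444. Its values in the arrays labelled GATA3 all lay under the detection level of 4, which makes it at least 1.66-fold lower. The other probe set (209603_at) read 2.44 ± 0.09 and 2.25 ± 0.09 (SD, n = 3) and was not tested. The readings of GATA3 thus go against the label. Probe sequences were not used here, so it is not known whether these probe sets read the introduced sequence or only the cell's own transcript. Every direction given below is that of the arrays labelled GATA3 against the GFP control arrays and rests on these labels.

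LOX, which encodes the secreted enzyme lysyl oxidase that cross-links collagen and elastin, was among the genes that fell most. Its brightest probe set (215446_s_at) read 11.65 ± 0.10 (SD, n = 3) in the GFP control and 5.85 ± 0.73 (SD, n = 3) in the arrays labelled GATA3. The log2 change was -5.80 (SE 0.36), 55.7-fold lower, with an adjusted p of 0.000326. The 2 other probe sets fell as well. Probe set 204298_s_at changed by -6.35 (81.6-fold lower, adjusted p 6.55e-06), and 213640_s_at by -3.96 (15.6-fold lower, adjusted p 0.00115). In the latter, 2 of the 3 arrays labelled GATA3 lay under the detection level, so that fold is uncertain. Other members of the lysyl oxidase family went both ways. LOXL1 rose from 8.85 ± 0.07 to 11.24 ± 0.16 (SD, n = 3), a log2 change of 2.39 (5.24-fold, adjusted p 6.17e-05), and LOXL4 fell by 0.69 on the log2 scale (adjusted p 0.0284). LOXL2 (0.18) and LOXL3 (0.60) did not pass the threshold. With 1 member higher and 2 lower of 5, the family had a median change of 0.18 and a mean of -0.66, and camera, whose direction was higher like the median, gave an adjusted p of 0.851. Adjusted over the list alone, 3 members were higher and 2 lower. The call of LOXL4 was lost when any 1 GFP control array was left out, with adjusted p-values of 0.0910, 0.0946 and 0.0917, which left 1 member lower. Without GATA3 replicate 2, after cyclic loess or with array weights, 2 members were higher, and 1 was lower without a filter on low values. With the suffix _at alone, 1 of 3 measured was higher and 1 lower.

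**Figure D1:**
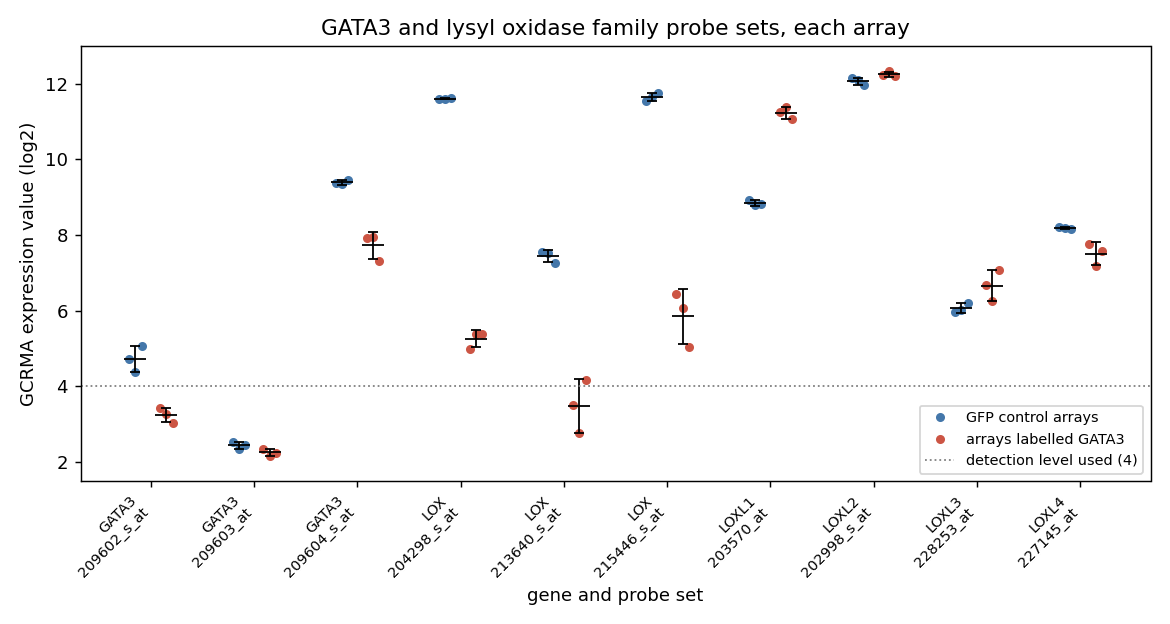
GCRMA expression values (log2) of every GATA3 and LOX probe set and of the probe set with the highest mean for LOXL1, LOXL2, LOXL3 and LOXL4, 1 point per array, with the mean (horizontal line) and SD (error bar) of the 3 GFP control arrays and the 3 arrays labelled GATA3; the dotted line marks the detection level of 4. GATA3 and LOX probe sets lie lower in the arrays labelled GATA3 (LOX 215446_s_at 5.85 against 11.65), while LOXL1 lies higher (11.24 against 8.85).

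Differences between the groups were widespread. Of 23785 tested probe sets, 6027 (25.3%) passed the threshold, 2698 higher and 3329 lower in the arrays labelled GATA3, and 835 were at least 2-fold higher and 815 at least 2-fold lower. With 1 probe set per gene, 3172 of 10814 genes changed, 1601 higher and 1571 lower, of which 457 were at least 2-fold higher and 330 at least 2-fold lower. The groups did not overlap in 10938 probe sets (46.0%), against the 10% that chance gives for 3 against 3. The count of lower probe sets was smaller in most fits with 1 array left out. It was 2018, 1892 and 1801 without GFP control replicates 1, 2 and 3 and 2182 without GATA3 replicate 2. The count of higher probe sets was 1796 without GFP control replicate 2. A fit with 1 array fewer has less power, so such drops need not come from the array left out. Without GATA3 replicate 3 the counts were 3581 higher and 3752 lower. The counts of 2-fold changes stayed between 764 and 896 higher and between 597 and 846 lower when any 1 array was left out.

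The genes with the largest rises were near or under the detection level in the GFP control and bright in the arrays labelled GATA3. MMP12, a macrophage-type metalloelastase, read 2.17 ± 0.01 in the GFP control and 12.11 ± 0.08 (SD, n = 3) in the arrays labelled GATA3, at least 276-fold higher (adjusted p 7.38e-07). ENTPD3, an enzyme that hydrolyses extracellular nucleotides, rose at least 312-fold (at least 20.6-fold by its other probe set), and NPPB, which encodes the precursor of brain natriuretic peptide, at least 143-fold. HSD3B1, a steroid dehydrogenase of placenta and skin, rose at least 175-fold. RGS5, a regulator of G protein signalling known from pericytes, rose 382-fold, from 4.41 ± 0.44 to 12.99 ± 0.21 (SD, n = 3, adjusted p 2.04e-05), although 1 of its 3 GFP control arrays was under the detection level. Its other tested probe sets rose less, 285-fold, at least 125-fold and at least 85.5-fold. The collagen-binding proteoglycan LUM rose at least 125-fold, ODAPH at least 101-fold, the prion-like protein gene PRND at least 67.4-fold (at least 36.5-fold by its other probe set) and the prostaglandin transporter SLCO2A1 at least 64.0-fold. Among these 12 genes were also 3 pregnancy-specific glycoproteins, PSG9 (at least 103-fold), PSG6 (at least 104-fold) and PSG3 (at least 64.2-fold). Their probe sets carry a suffix for probes shared between similar transcripts, and this family has near-identical copies, so which of its members rose is uncertain. The probe set of PSG9 without that suffix rose less, 4.05-fold, from 4.96 to 6.98, and that of PSG6 rose at least 7.27-fold, from 3.29 to 6.86. The rank of these 12 genes used fitted changes, mostly from values under the detection level. PSG5, not among them, rose at least 92.8-fold, above the bounds of PSG3, PRND and SLCO2A1. Rank and number of PSG genes among the 12 are therefore uncertain.

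The largest falls, ranked by fitted log2 change, included matrix and junction genes. Most of them reached values under the detection level, so their rank is uncertain. CDH11, 16.5-fold lower with both groups over that level, ranked below them. PXDN, a peroxidase that cross-links collagen IV, fell from 9.81 ± 0.14 to 3.83 ± 0.27 (SD, n = 3), at least 56.3-fold lower (adjusted p 1.74e-05; at least 15.5-fold by its other probe set). GJA1, which encodes the gap junction protein connexin 43, was at least 37.2-fold lower, and CEMIP, a protein needed for the breakdown of hyaluronan, at least 22.6-fold lower. The hyaluronan synthase HAS2 was at least 9.06-fold lower (at least 5.20-fold by its other probe set). The RNA-binding protein gene CELF2 was at least 28.7-fold lower, the presynaptic gene PCLO at least 13.6-fold (at least 5.57-fold by its other tested probe set), the chromatin organiser SATB1 at least 10.4-fold, and IGDCC4 at least 6.16-fold. NNMT, nicotinamide N-methyltransferase, fell 21.6-fold, from 11.62 ± 0.03 to 7.19 ± 0.19 (SD, n = 3), and 53.2-fold by its other probe set. TMEM71 was 26.8-fold lower, with 2 of its 3 arrays labelled GATA3 under the detection level. The pseudogene DUXAP10 was at least 14.03-fold lower, and its probe set also carries the suffix for shared probes, so its identity is uncertain. Its other tested probe set, without that suffix, was at least 2.34-fold lower (adjusted p 0.000715). These falls, like that of LOX, were seen in all 3 arrays labelled GATA3, but the rule that chose these genes required this.

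**Figure D2:**
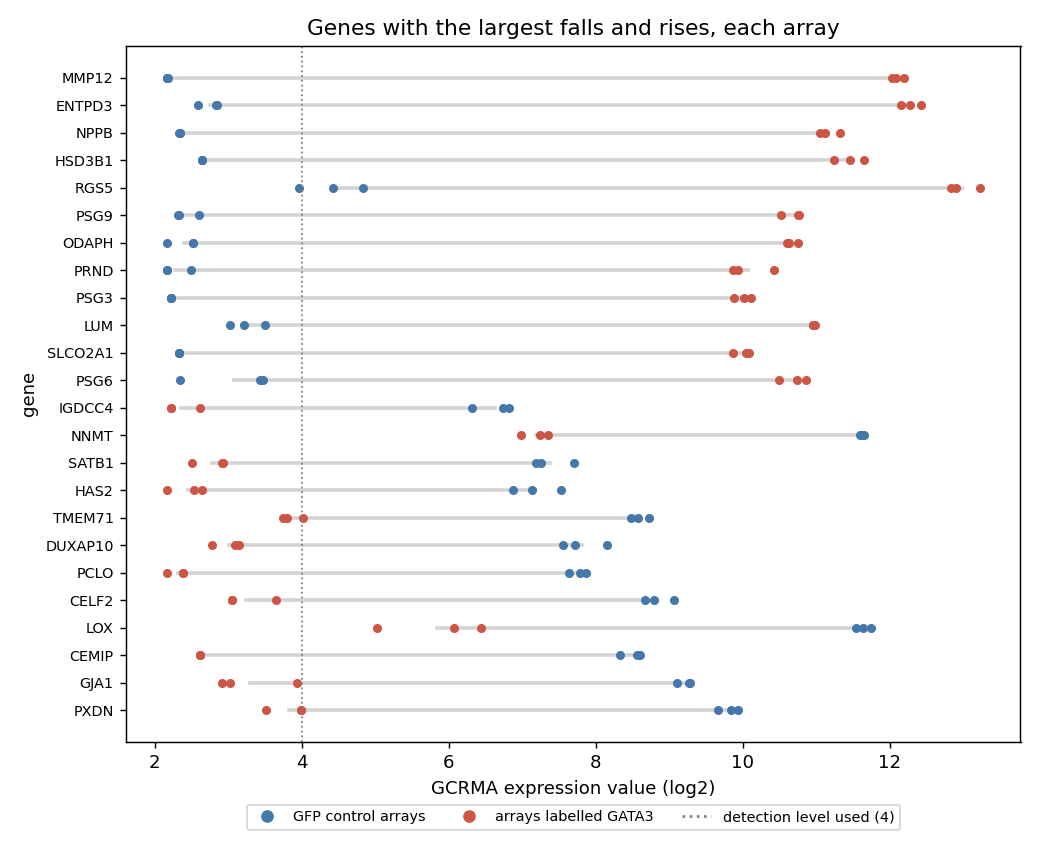
GCRMA expression values (log2) of the 12 genes with the largest rises and the 12 with the largest falls, 1 point per array for the 3 GFP control arrays and the 3 arrays labelled GATA3; the grey line joins the group means and the dotted line marks the detection level of 4. By the rule that chose these genes, the arrays of the groups do not overlap in any of them, and MMP12 goes from 2.17 to 12.11.

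The clearest gene group was that of epithelial junctions. Of 18 measured members of a list of 30, 16 rose, none fell and 2 did not pass the threshold, with a median log2 change of 1.40 (camera, higher, adjusted p 2.89e-10). The adjusted p was 0.153 with an estimated correlation, and 17 were higher when adjusted over the list alone. With probe sets of the suffix _at alone, 11 members were measured and 9 rose. ESRP1, GRHL1, GRHL2, OVOL1, RAB25, LAD1, TJP3, MARVELD3 and DSC2 had probe sets but none over the detection level in enough arrays to be tested. A member silent in the GFP control was counted only if it came on in the arrays labelled GATA3, so the share that rose holds for measured members alone. CDH1, which encodes E-cadherin, rose from 2.35 ± 0.00 to 7.40 ± 0.69 (SD, n = 3), at least 10.5-fold (adjusted p 0.000417). OVOL2, a transcription factor that represses mesenchymal genes, rose at least 12.96-fold, from 2.47 to 7.70. CDS1, an enzyme of phospholipid synthesis, rose 8.12-fold and the tight junction gene OCLN 5.81-fold, from 8.49 ± 0.16 to 11.03 ± 0.16 (SD, n = 3). Other tested probe sets of these 2 genes rose 4.37-fold to 8.34-fold for CDS1 and 3.66-fold to 7.75-fold for OCLN.

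Mesenchymal genes were lower. Of 12 measured, 7 fell, none rose and 5 did not pass the threshold, with a median of -0.28 (camera, lower, adjusted p 0.00132). The call was lost with an estimated correlation (adjusted p 0.153), and 7 were lower adjusted over the list alone. With the suffix _at alone, 6 were measured and 4 fell. SNAI1, TWIST1, TWIST2, SPARC, MMP2, FAP, THY1, POSTN, TCF4 and PRRX1 had probe sets but none over the detection level in enough arrays to be tested. CDH11, a mesenchymal cadherin, fell 16.5-fold, from 10.98 ± 0.07 to 6.93 ± 0.24 (SD, n = 3, adjusted p 3.12e-05), and 9.09-fold and at least 3.78-fold by its other tested probe sets. ZEB1, a repressor of E-cadherin, fell 3.77-fold, from 11.06 ± 0.05 to 9.14 ± 0.05 (SD, n = 3). TGFBI fell 3.36-fold and S100A4 1.88-fold, from a high level of 14.40 to 13.49.

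Luminal markers went both ways. Of 15 measured, 6 rose, 2 fell and 7 did not pass the threshold, with a median of 0.15, and camera gave an adjusted p of 0.182. Adjusted over the list alone, 6 were higher and 3 lower. ERBB3, a receptor of the epidermal growth factor receptor family, rose 7.48-fold, from 4.34 ± 0.02 to 7.24 ± 0.38 (SD, n = 3). Of its other tested probe sets, 1 rose at least 4.75-fold and 1 had a change of 0.00 (adjusted p 0.994). The latter read the same 4.70 on every GFP control array, which may be background. The luminal keratin KRT19 rose 2.12-fold, from 12.12 to 13.20. The other rises were smaller on the log2 scale. They were NAT1 (0.67, adjusted p 0.00264), KRT8 (0.60, adjusted p 0.00908), KRT18 (0.52, adjusted p 0.000503) and MLPH (0.35, adjusted p 0.00868). AGR2 fell 6.18-fold, from 8.26 ± 0.07 to 5.64 ± 0.37 (SD, n = 3), and the mucin gene MUC1 fell 2.21-fold (at least 2.68-fold by its other tested probe set). The 7 members that did not pass were XBP1 (0.03), TBC1D9 (-0.11), SLC39A6 (-0.01), SPDEF (0.06), KRT7 (0.27), CA12 (-0.56) and the oestrogen receptor gene ESR1. ESR1 lay barely over the detection level, at 4.02 on each GFP control array and 4.16 ± 0.25 (SD, n = 3) in the arrays labelled GATA3 (log2 change 0.15, adjusted p 0.441). The repeated value may be background, so expression of ESR1 was not shown. PGR, FOXA1, TFF1, TFF3, GREB1, PRLR, ELF3, ELF5, SCUBE2 and MYB had probe sets but none over the detection level in enough arrays to be tested. With the suffix _at alone, 8 members were measured, 3 higher and 2 lower, and 4 were lower with array weights by the default method, which did not converge.

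Basal and myoepithelial markers were higher. Of 12 measured, 8 rose, none fell and 4 did not pass the threshold, with a median of 0.37 (camera, higher, adjusted p 0.0105). It was lost with an estimated correlation (adjusted p 0.192), and 8 were higher and 1 lower adjusted over the list alone. KRT14, a basal keratin, rose at least 7.25-fold, from 2.38 ± 0.06 to 6.86 ± 0.33 (SD, n = 3, adjusted p 6.17e-05). The other named members rose less, KRT15 1.84-fold, MIA 1.93-fold and MYLK, the myosin light chain kinase gene, 1.54-fold. KRT5, KRT16, MME, CNN1, CDH3, CRYAB and KIT had probe sets but none over the detection level in enough arrays to be tested. The call of MIA was lost without GFP control replicates 1 or 2 or GATA3 replicates 2 or 3, with adjusted p-values of 0.0525, 0.0558, 0.0811 and 0.0557. The number of higher members was 4 without GFP control replicate 1, 5 without GFP control replicate 2 and 4 without GATA3 replicate 2, and 1 member was lower without GATA3 replicate 3. The number higher was 4 without a filter on low values and 5 of 10 measured with the suffix _at alone, and 1 to 2 were lower with array weights or the mean of all probe sets.

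**Figure D3:**
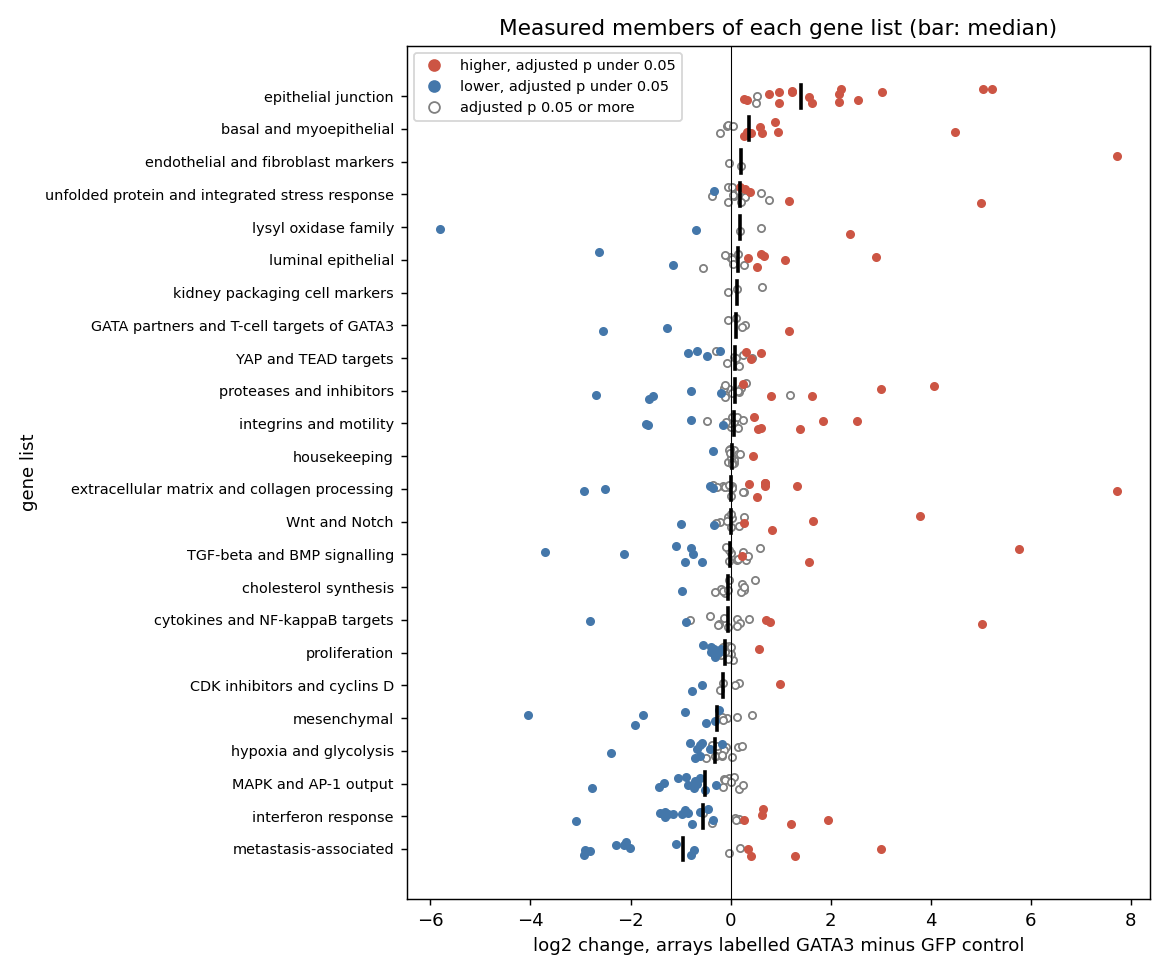
Log2 change (arrays labelled GATA3 minus GFP control) of every measured member of the 24 lists tested, 1 point per gene, ordered by the list median (black bar); filled points passed an adjusted p of 0.05 (red higher, blue lower) and open points did not. The epithelial junction list has the highest median (1.40) and the metastasis-associated list the lowest (-0.95).

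Genes associated with metastasis of breast cancer cells mostly fell. Of 16 measured, 10 fell, 4 rose and 2 did not pass the threshold, with a median of -0.95 (-0.75 with genes under the detection level set at their bound). Camera gave an adjusted p of 0.0872, which did not pass. Adjusted over the list alone, 4 were higher and 10 lower. The matrix glycoprotein gene TNC fell 7.67-fold, from 8.50 ± 0.14 to 5.56 ± 0.34 (SD, n = 3). The cytokine gene IL11 fell 7.05-fold, from 8.35 ± 0.60 to 5.53 ± 0.18 (SD, n = 3), but 1.50-fold by its other, dimmer probe set (adjusted p 0.0373). The growth factor gene FGF5 fell by 2.90 on the log2 scale (adjusted p 0.00550), with 2 of its 3 arrays labelled GATA3 under the detection level, and was at least 2.79-fold lower by its other tested probe set. MMP1, interstitial collagenase, rose 8.04-fold, from 5.11 ± 0.33 to 8.12 ± 0.14 (SD, n = 3). The call of the whole list depended on the scaling. It passed with each array centred on its median (adjusted p 0.0134) or on its 75th percentile (0.0104), after quantile normalization (0.0344) or cyclic loess (0.0287), and without GFP control replicate 2 (0.0481).

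Extracellular matrix and collagen processing genes showed no common direction. Of 24 measured, 7 rose, 4 fell and 13 did not pass the threshold, with a median of 0.02, and camera gave an adjusted p of 0.613. Adjusted over the list alone, 8 were higher and 4 lower, and with the suffix _at alone 5 of 16 measured were higher and 2 lower. Besides LUM and TNC, the named members were COL8A1, a short-chain collagen, which fell 5.72-fold from 10.98 ± 0.02 to 8.46 ± 0.19 (SD, n = 3; at least 7.63-fold and at least 4.52-fold by its other probe sets), and the laminin chain gene LAMA5, which rose 2.51-fold. Of 20 measured proteases and inhibitors, 5 rose and 5 fell (median 0.08, camera adjusted p 0.574), and 7 were higher and 5 lower adjusted over the list alone. MMP3, stromelysin, rose at least 7.39-fold and ADAM12 at least 1.93-fold (its other tested probe set had a change of 0.71, adjusted p 0.0569), while the protease inhibitor gene SERPINE2 fell 6.44-fold. Among 21 integrins and motility genes, 6 rose and 4 fell (median 0.06, camera adjusted p 0.359), and 7 were higher and 4 lower adjusted over the list alone. The collagen receptor chain ITGA2 rose 5.77-fold and ITGB8 at least 2.05-fold, a call lost without the filter on low values (adjusted p 0.0502), whereas the fibronectin receptor chain ITGA5 fell 3.16-fold and the small GTPase gene RHOB 3.24-fold. The other tested probe set of RHOB had a change of -0.18 and did not pass (adjusted p 0.175), and the mean of both was -0.94.

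Targets of mitogen-activated signalling and of hypoxia were lower. Of 21 measured genes of MAPK and AP-1 output, 12 fell and none rose (median -0.51, camera adjusted p 0.000461). With an estimated correlation the adjusted p was 0.291, and adjusted over the list alone 12 were lower. The feedback inhibitor genes SPRY1 and SPRY4 fell 6.85-fold and 2.52-fold (the other tested probe set of SPRY1 had a change of -0.38, adjusted p 0.174, and the mean of both was -1.58), the transcription factor gene ETV4 2.70-fold and the phosphatase gene DUSP6 2.06-fold. Of 21 hypoxia and glycolysis genes, 9 fell and none rose (median -0.31, camera adjusted p 0.000361). With an estimated correlation the adjusted p was 0.153, and adjusted over the list alone 15 were lower and 1 higher. Without GATA3 replicates 1 or 3, 1 was higher. NDRG1 fell 5.27-fold, from 10.70 ± 0.07 to 8.30 ± 0.08 (SD, n = 3), and the glucose transporter gene SLC2A1, PFKFB3 and DDIT4 fell 1.75-fold, 1.63-fold and 1.59-fold.

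Proliferation genes changed little in size. Of 25 measured, 7 fell and 1 rose (median -0.12, camera, lower, adjusted p 0.0359). With an estimated correlation the adjusted p was 0.255, and adjusted over the list alone 8 were lower and 1 higher. The call was lost with the arrays centred on their medians (adjusted p 0.177) and without GATA3 replicates 1 or 2 (adjusted p 0.0860 and 0.0571). With any 1 array left out, 3 to 4 members were lower instead of 7. MCM4 fell 1.46-fold, CDC20 1.32-fold and FOXM1 1.31-fold, and CCNE1, a cyclin of entry into S phase, rose 1.49-fold. Of 7 inhibitors of cyclin-dependent kinases and D cyclins, 1 rose and 2 fell (median -0.15, camera adjusted p 0.926), and 2 were higher and 2 lower adjusted over the list alone. CDKN1A rose 1.97-fold, CDKN1C fell 1.72-fold and CDKN1B fell 1.49-fold. Without GATA3 replicate 3, 2 were higher, and without GFP control replicate 2, 1 was lower. The calls of MCM4 were lost without GFP control replicates 1 or 2 (adjusted p 0.0556 and 0.0590), that of CDKN1B without GFP control replicate 2 (0.0572), and that of FOXM1 without GFP control replicates 1 or 3 (0.0595 and 0.0647).

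Genes of the interferon response were mostly lower. Of 23 measured, 13 fell, 5 rose and 5 did not pass the threshold (median -0.56, camera, lower, adjusted p 0.0359). With an estimated correlation the adjusted p was 0.433, and adjusted over the list alone 14 were lower and 5 higher. OAS2 fell 8.47-fold, from 7.66 ± 0.05 to 4.57 ± 0.07 (SD, n = 3), and IFIT1 and IFI44 fell 2.67-fold and 2.50-fold. IFI27 went the other way and rose 3.84-fold, from 9.05 ± 0.03 to 10.99 ± 0.08 (SD, n = 3). The call of the list was lost without GFP control replicate 1 (adjusted p 0.0552), and 3 members were higher without GFP control replicates 2 or 3 or GATA3 replicate 2.

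Of 20 measured genes of TGF-beta and BMP signalling, 3 rose and 7 fell (median -0.02, camera adjusted p 0.953), and 4 were higher and 7 lower adjusted over the list alone. Without GATA3 replicate 3, 6 were higher, and 4 were lower without GFP control replicate 1 or GATA3 replicates 1 or 2. The activin chain gene INHBA rose at least 47.9-fold, from 3.82 ± 0.16 to 9.58 ± 0.25 (SD, n = 3; at least 10.4-fold by its other tested probe set), and ID2 rose 2.97-fold. INHBB was at least 6.75-fold lower, from an uneven 6.75 ± 1.44 in the GFP control (SD, n = 3), and LTBP1, which encodes a binding protein of latent TGF-beta, fell 4.41-fold. The fitted log2 change of INHBB was -4.53 to -3.19 with 1 array left out, sizes that reach under the detection level. Its call was lost without GFP control replicates 1 or 2 or GATA3 replicates 1 or 2 (adjusted p 0.0610, 0.0773, 0.0518 and 0.0677). Of 7 measured genes among partners of GATA factors and GATA3 targets of T cells, 1 rose and 2 fell (median 0.11, mean -0.29, camera, higher, adjusted p 0.990), as they did adjusted over the list alone. Without GATA3 replicate 3, 2 were higher. GATA6 fell 5.83-fold, from 10.53 ± 0.17 to 7.99 ± 0.05 (SD, n = 3), LMO4 fell 2.41-fold, and GATA2 rose 2.26-fold, from 8.68 ± 0.14 to 9.86 ± 0.02 (SD, n = 3), while its other tested probe set had a change of 0.74 (adjusted p 0.0577).

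Markers of other cell types gave few readings. Of 17 leukocyte markers 2 were measured and neither passed, with 0 higher or lower adjusted over the list alone, among them CD79B at 4.73 ± 0.03 and 4.74 ± 0.31 (SD, n = 3). Of 14 endothelial and fibroblast markers 3 were measured, and LUM alone rose (median 0.22, camera adjusted p 0.182; 1 higher adjusted over the list alone). Of 13 markers of kidney-derived packaging cells 3 were measured and none passed (median 0.13, camera adjusted p 0.763). PAX8 was at 5.34 ± 0.07 and 5.29 ± 0.02 (SD, n = 3). It read the same 5.303 on GFP control replicates 1 and 2 and GATA3 replicates 2 and 3, which may be background. Of these markers, 0 were higher or lower adjusted over the list alone, and 1 was higher without GATA3 replicate 3. Of 16 housekeeping genes, 1 rose and 1 fell (median 0.03, camera adjusted p 0.421), and 1 was higher adjusted over the list alone. Without GATA3 replicate 1, 2 were higher. HPRT1 rose 1.36-fold and POLR2A fell 1.27-fold. The call of POLR2A was lost under each of the 4 other scalings, the highest adjusted p being 0.135, and without any 1 array except GFP control replicate 2, the highest adjusted p being 0.129.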

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

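All alternatives but 1 were planned before the data were examined, and array weights by the gene-by-gene method were added after seeing the data. The fall of the GATA3 probe set (-1.76 to -1.45) and of LOX (-6.10 to -5.37) kept its direction and its side of the threshold under every alternative run. The counts of 2-fold changes stayed at 686 to 952 higher and 570 to 858 lower. Of 100 named genes past the threshold, 86 stayed past it under every alternative, 11 lost it when 1 array was left out, 14 lost it under another alternative (some under both), and 0 changed sign. Without a filter on low values, 13 lost it (MIA, LOXL4, INHBB, MCM4, FOXM1, CDKN1B, PPP1R15A, LATS2, F3, TEAD1, RNF43, ITGB8 and POLR2A). With the replicate block MIA, LOXL4, INHBB, CDKN1B, ITGB8 and POLR2A lost it, and with the date block MIA, RNF43 and POLR2A. GATA3 replicate 3 is the only array of the second raw-file date set, so the date block nearly equals leaving that array out (3581 higher under both, 3747 and 3752 lower) and is not a separate alternative. Of 47 named genes with over 1 tested probe set, 27 had another whose fitted change differed by over 1.5-fold. In 9 called genes another tested probe set did not pass (ADAM12, CDKN1C, DNAJB9, ERBB3, GATA2, LATS2, PPP1R15A, RHOB and SPRY1), and in 0 did another pass with the opposite sign. Of 994 recomputed counts of list members, 825 stayed within 1.5 times, 82 were smaller and 87 larger. With the replicate block 5 basal members were higher, 1 was lower with either block, and 1 of the lysyl oxidase family was lower with the replicate block. The floor of the values and the detection level limit what can be said of dim probe sets.

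The count of lower probe sets was 1767 without a filter on low values and 2106 with the replicate block, under which 2022 were higher. Array weights gave 5195 higher and 6642 lower, but the default method stopped before it converged and gave GATA3 replicate 2 a weight of 11.8, so these counts are not reliable. The gene-by-gene method gave 4264 higher and 5123 lower, with a weight of 0.159 for GATA3 replicate 3. The cause of the other differences was not tested. With 1 array left out, the counts were 1796 to 3581 higher and 1801 to 3752 lower, each from 5 arrays. Samples of the same number did not deviate together (correlations of -0.135, 0.159 and -0.109), so the replicate numbers were not taken to pair them.

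The metastasis-associated list passed with an adjusted p of 0.0134 centred on the median, 0.0104 centred on the 75th percentile, 0.0344 after quantile normalization, 0.0287 after cyclic loess and 0.0457 with the replicate block, and had 0.0481 to 0.161 with 1 array left out; its range over all alternatives was 0.00118 to 0.394. The basal list had 0.0509 with probe sets of the suffix _at alone and 0.192 with an estimated correlation (range 0.000197 to 0.192). The mesenchymal and epithelial junction lists both had 0.153 with an estimated correlation. Fry, which does not compare a list with other genes, gave 0.00280 for the luminal, 0.00511 for the lysyl oxidase family, 0.00441 for the extracellular matrix and 0.00118 for the metastasis-associated list. It also passed for the proteases (0.000155), integrins (0.00344), cytokines (0.0127), Wnt and Notch genes (0.0119) and endothelial and fibroblast markers (7.84e-05), none of which passed with camera. Among the secondary lists, the proliferation call was lost with a filter at 6 (0.0620), centred on the median (0.177) or the 75th percentile (0.192), without the trend (0.0526) and with the suffix _at (0.177). The suffix _at also ended the calls of the hypoxia (0.0509) and unfolded protein (0.278) lists, and a filter at 6 that of the interferon list (0.104). The cause of these differences was not tested.

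Lists and genes that had not passed changed direction as follows, with adjusted p-values for lists; the cause was not tested. Ranges with 1 array left out cover all 6 such fits, and the number of them that changed direction is given. YAP and TEAD targets had 0.996 without a filter, 0.855 centred on the median, 0.833 on the 75th percentile, 0.921 after quantile normalization, 0.946 after cyclic loess, 0.955 with array weights (0.949 gene by gene), 0.903 with the date block, 0.916 with the suffix _at, and 0.545 with fry. With 1 array left out it had 0.802 to 0.997 and changed direction in 2 of 6 fits (without GFP control replicate 1 or GATA3 replicate 3). GATA partners had 0.673 with a filter at 6, 0.855 and 0.833 after centring, 0.957 after quantile normalization, 0.983 after cyclic loess, 0.916 with the suffix _at, and 0.00618 with fry. With 1 array left out they had 0.903 to 0.994 and changed direction in 3 of 6 fits (without GFP control replicates 1 or 2 or GATA3 replicate 2). Cholesterol synthesis had 0.992 after cyclic loess, 0.964 with array weights (0.986 gene by gene), 0.990 with the replicate block, 0.903 with the date block, and 0.947 with the mean of all probe sets. Its range with 1 array left out was 0.816 to 0.994, and 2 of 6 fits changed direction (without GFP control replicate 1 or GATA3 replicate 3). Cytokines had 0.858 without a filter, 0.997 with array weights by either method, 0.903 with the date block, and 0.563 with the suffix _at. Their range with 1 array left out was 0.759 to 0.994, and 1 of 6 fits changed direction (without GATA3 replicate 3). TGF-beta and BMP signalling had 0.964 with array weights and 0.908 with fry, CDK inhibitors 0.953 with a filter at 6, and integrins 0.962 with the mean of all probe sets. The log2 change of PAX8 was 0.029 centred on the median, 0.040 on the 75th percentile, 0.00604 after quantile normalization and 0.0032 after cyclic loess. That of CD79B was -0.022 with array weights (-0.070 gene by gene), and -0.15 with the date block. With 1 array left out it was -0.15 to 0.16, and 1 of 6 fits changed direction (without GATA3 replicate 3).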

Other observations

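Several lists not described above held single large changes. Of 15 measured cytokine genes and NF-kappaB targets, 3 rose and 2 fell (median -0.06, mean 0.11, camera, higher, adjusted p 0.926), also when adjusted over the list alone. TNFAIP3, which encodes an inhibitor of NF-kappaB signalling, rose 32.4-fold, from 5.97 ± 0.26 to 10.98 ± 0.08 (SD, n = 3), and 55.1-fold by its other probe set, IL32 rose 1.71-fold and CSF1 fell 1.85-fold (2.99-fold and 3.21-fold by its other probe sets). Of 17 genes of the unfolded protein and integrated stress response, 5 rose and 1 fell (median 0.19, camera, higher, adjusted p 0.0318), also when adjusted over the list alone. With an estimated correlation the adjusted p was 0.221. The number of higher members was 8 without GATA3 replicate 3 and 3 without any 1 GFP control array or GATA3 replicate 1, and 0 were lower without any 1 GFP control array or GATA3 replicate 2. The lipoprotein receptor gene VLDLR rose 32.1-fold, from 6.57 ± 0.16 to 11.58 ± 0.16 (SD, n = 3), the cystine transporter gene SLC7A11 2.24-fold and DNAJB9 1.31-fold. The call of DNAJB9 was lost with probe sets of the suffix _at alone (adjusted p 0.277). By contrast, PPP1R15A fell 1.26-fold, a call lost without any 1 GFP control array or GATA3 replicate 2 (highest adjusted p 0.0762).

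Of 15 Wnt and Notch genes, 4 rose and 2 fell (median 0.01, camera adjusted p 0.534), also when adjusted over the list alone. Without GFP control replicate 2 or GATA3 replicate 1, 1 was lower. The Notch target HEY1 rose at least 6.85-fold, the Notch ligand gene JAG2 3.11-fold and RNF43 1.79-fold, and TCF7L2 fell 1.99-fold. The call of RNF43, for which 2 of 3 GFP control arrays were under the detection level, was lost without GFP control replicates 2 or 3 or GATA3 replicates 1 or 3 (highest adjusted p 0.144). Of 14 YAP and TEAD targets, 3 rose and 4 fell (median 0.09, mean -0.02, camera, higher, adjusted p 0.965), also when adjusted over the list alone. NT5E fell 1.81-fold (1.28-fold to 3.55-fold by its other tested probe sets), LATS2 1.60-fold and TEAD1 1.38-fold, and F3, tissue factor, rose 1.53-fold. The other 2 tested probe sets of TEAD1 fell 3.92-fold and 2.97-fold, and the call of TEAD1 was lost without the filter on low values (adjusted p 0.0501). With either GFP control replicate 2 or 3 left out, 1 target was higher and 2 were lower, and 1 was higher without GATA3 replicate 2. The call of F3 was lost without any 1 GFP control array or GATA3 replicate 2 (highest adjusted p 0.108), and that of LATS2 without GFP control replicates 2 or 3 (adjusted p 0.0549 and 0.0528). Of 12 genes of cholesterol synthesis, 1 fell (median -0.04, camera adjusted p 0.965), also when adjusted over the list alone. It was INSIG1, 1.95-fold lower. Without GATA3 replicate 3, 3 were higher and 2 lower.

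Of the tests that follow, those of the GATA3 probe sets, of the LOX probe sets and of the placental genes were chosen only after the result had been seen. The intervals set around the hypoxia median and the window share were added after those values had been seen, and neither reading changed with them.

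GATA3 probe sets were lower in the arrays labelled GATA3. One candidate explanation is an exchange of the labels of the groups. LOX, which the title names as suppressed by GATA3, changed by -5.80 in the direction of the title. The title may rest on these same labels, so this leaves an exchange open. The cell line is of mesenchymal-like character, and the GFP control arrays were the more mesenchymal ones. In the arrays labelled GATA3, 16 of 18 junction genes were higher and 7 of 12 mesenchymal genes lower. This goes with the labels as given. Basal markers, 8 of 12 higher, went the other way for a basal line, and cells without a lentivirus were not measured. Another candidate explanation is that the probe sets read only the cell's own transcript and not the introduced sequence. No tested probe set rose, which such blindness allows, but both fell. The one that fell least had a fitted change of -1.48, into values under the detection level, and was at least 1.66-fold lower. The other fell 3.16-fold. Blindness alone gives no fall, so this explanation also needs a fall of the cell's own transcript, which was not tested. Probe sequences were not used here, and these explanations cannot be told apart.

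The number of changed probe sets was large. The real grouping gave 6027, and the highest count among the other splits of the 6 arrays was 0. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Gain or loss of chromosome segments in either pool of cells may shift neighbouring genes together. Of 786 genes changed at least 2-fold, 61 (7.76%, exact binomial 95% interval 5.99 to 9.86) lay in windows of 25 neighbouring genes shifted by over 0.2 in the same direction. This argues against segments as the source of most of these 2-fold changes. Genes that changed by under 2-fold were not counted, so the share does not speak for them. The window medians reached at most 0.41 and at least -0.35, well short of 2-fold. Few genes could reach 2-fold through such shifts alone, so a low share says little about whether segments were gained or lost. Of 432 windows, 28 (6.48%) were shifted, against at most 2.55% over 1000 shuffled gene orders, so some of the changes may still follow position.

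LOX was lower in the arrays labelled GATA3. A single probe set reading another transcript is argued against, since all 3 LOX probe sets fell. The one that fell least changed by -3.96, a size made uncertain by values under the detection level. The others changed by -5.80 and -6.35. Lower hypoxia signalling may contribute. The hypoxia and glycolysis list, which holds no LOX, had a median of -0.31, past the -0.3 set beforehand, with 18 of 21 members below 0. The bootstrap 95% interval was -0.57 to -0.17, the median over alternatives was -0.38 to -0.22, and both reach values short of -0.3. The largest fall in the list, -2.40 for NDRG1, was smaller than the -5.80 of LOX, and a direct effect of GATA3 on LOX was not tested.

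GATA3 replicate 3 stood apart from the other 2 arrays of its group. It differed from their mean by over 1 on the log2 scale in 923 tested probe sets, 673 of them lower, against at most 96 for a GFP control replicate. A smaller response in that sample, over rises and falls together, is argued against. The median ratio of its change to that of the other 2 arrays was 0.980 over 1564 probe sets that the 5 other arrays called at least 2-fold. Rises and falls were pooled, so a downward shift of the array could offset a smaller response among raised genes, which was not tested apart. Lower RNA quality may contribute and stays open. Its 3' to 5' ratio of GAPDH lay above those of the 5 other arrays by 0.127 of their range, while that of ACTB lay within their range. Without this array, 801 of the 835 probe sets at least 2-fold higher and 635 of the 815 at least 2-fold lower were called again.

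Pregnancy-specific glycoproteins and HSD3B1 among the largest rises raised the hypothesis that a wider placental programme may be higher. A list of 58 trophoblast genes was written after those rises had been seen. Of its 27 measured members, 17 rose and 1 fell (median 1.32, camera p 1.59e-10, and p 0.00199 with an estimated correlation), but this set includes the genes that raised the hypothesis and PSG probe sets that share probes. Over the 12 measured members that had not been seen, 3 rose and 1 fell, with a median of 0.02 and a camera p of 0.274 (p 0.377 with an estimated correlation), which leaves the hypothesis open. These 12 leave out PSG genes, members of the gene lists and genes among the 40 largest rises or falls. Strong rises such as that of HSD3B1 were thus removed by rule, which biases the subset towards no rise. A first version of that subset also held PAPPA, which had been seen among the large rises. It gave 4 higher and 1 lower of 13, a median of 0.05 and a camera p of 0.0902, and was first read as counting against the hypothesis. Both the subset and the rule for reading it were changed after that result.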
